A study of Rattus norvegicus with 10 samples.

How the data were processed

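Liver RNA of 10 male Wistar rats was measured on Agilent whole rat genome 4x44K oligonucleotide arrays in 1 colour (Cy3), with 1 array per rat and 150 ng of total RNA labelled per array. Of the rats, 5 had received vehicle only (control) and 5 had received diethylnitrosamine followed by thioacetamide (DEN/TAA), per the labels. The labels number the replicates within each group and describe the treated ones as animals, so each array was taken as 1 rat. The p-values of single genes and of permutation tests measure the spread between these rats.

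The deposited scanner files hold spot intensity, written by Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 15.5. The processed signal intensity is background-subtracted within the array per the file headers, and is not yet scaled between arrays. A second deposited table holds log2 values made by the authors. In each of its columns the rank order matched that of the same array's raw median spot intensity (Spearman's rho of 1 across spots), and the column medians lay between 8.592 and 8.594. It thus holds quantile-normalised log2 signal without background subtraction, with a known direction, and it was used as an alternative. The step that made it is not given in the sources used here. Slides and scans were read from the files: the arrays lay on 3 slides, each scanned as 1 batch. Slide 1 held control replicates 1 and 2 and DEN/TAA replicates 1 and 2, slide 2 held control replicate 3 and DEN/TAA replicates 3 and 4, and slide 3 held control replicates 4 and 5 and DEN/TAA replicate 5.

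From these files, spots with an outlier flag and control spots were left out, the log2 processed signals of all spots of 1 probe were averaged, and each array's 75th percentile was subtracted. Because at most 46.6% of spots were well above background on any array, the percentile was taken over the 6232 probes that were well above background on all 10 arrays. The planned design had not named the probe set, and the percentile over all probes was added as an alternative after the arrays had been seen. A probe was kept when it was well above background on at least 5 of the 10 arrays. No spot was saturated. Probes were named through the RefSeq accession in the array design, matched without versions to NCBI RefSeq genes of the rat assembly GRCr8. Of 41012 probes, 17502 had 1 gene symbol, 0 had several and 23510 had none here. They named 13832 genes, of which 2984 had more than 1 probe, and such a gene was represented by its passing probe with the highest mean over all arrays. No coordinates are given, since the array was annotated on another genome build.

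Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all 6849 genes tested, threshold 0.05) on all 10 arrays without covariates. Log2 differences are DEN/TAA minus control. A gene that was not well above background on any array of a group has only a bound there. It is given as at least N-fold, comparing the brighter group's mean with the dimmer group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. For named genes above background on only some arrays of the lower group, raising its other arrays to that floor was added after the data were seen. Before the data were examined, 38 gene lists were fixed, and the 35 with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. At that preset, camera's p-values set a list's members against other genes, and do not by themselves measure the spread between rats. Camera with an estimated correlation and fry were alternatives. List scores (the mean log2 value over measured members in a rat), a pericentral minus periportal score and the spread between rats were compared with two-sided exact permutation tests over all 252 assignments of 5 rats to a group, for which the smallest possible p is 0.00794.

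The genes named were set by a rule fixed in advance: the 10 largest rises and the 10 largest falls among genes past the threshold, without overlap between the groups, above background on all arrays of the brighter group and with a symbol that is no placeholder; per list, up to 2 changed members in each direction with the smallest adjusted p; and 13 sentinel genes whatever their result. This gave 113 tested genes, of which 1 is not reported here. Of the sentinels, Acta2 and Mki67 had no named probe here, and Tgfb1 did not pass the filter, so none of these is reported.

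The alternatives planned in advance were normexp background correction, quantile normalisation, the authors' table, no filter and a filter on all 10 arrays, the mean over a gene's probes, slide and replicate number as blocks, a trended robust prior, array weights, other set tests, and leaving out each rat in turn. Normexp, with an offset of 50, was run on the median spot signal in place of the planned mean signal, a column not used here. Added after the arrays had been seen were the percentile over all probes, scaling to the 5 brightest spike-in probes, and a fit without the 2 dimmest control arrays. On simulated arrays with the real means and residual spreads of the 6849 genes, 200 of them changed in the comparison of DEN/TAA with control, limma recovered 12% of genes changed by 0.5 on the log2 scale, 52% of those raised by 1, 58% of those lowered by 1 and 88% of those raised by 2. Of its calls, 4.55% were false. The simulation gave genes independent noise, arrays equal brightness and few changed genes, while 55.3% of genes were called in the data. Its shares therefore do not cover errors from scaling and need not hold for the real comparison. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The number of arrays limits the precision of every value.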

Results

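Gene expression was measured in the livers of 5 vehicle-treated control rats and 5 rats given DEN/TAA, a protocol that the series title presents as a model of cancer arising in cirrhosis. Diethylnitrosamine is a DNA-alkylating liver carcinogen and thioacetamide a toxin that hepatocytes activate and that scars the liver. Treated rats received 1 intraperitoneal dose of 200 mg/kg diethylnitrosamine at 6 weeks of age. From 2 weeks later they received 200 mg/kg thioacetamide in cycles of 3 weeks on and 1 week off, during 23 weeks. The labels also give the age of every rat as 23 weeks, which a treatment of 23 weeks begun at 6 weeks of age would exceed, so the duration is not settled here.

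The control arrays were dimmer than the DEN/TAA arrays. The share of spots well above background was 25.5% ± 6.21 (SD, n = 5) in control and 40.6% ± 4.42 (SD, n = 5) in DEN/TAA, without overlap (two-sided exact permutation test, p = 0.00794, the smallest it can give). The 75th percentile of signal over detected probes was 10.79 ± 0.69 in control and 12.26 ± 0.36 in DEN/TAA on the log2 scale (SD, n = 5 each). The 5 brightest spike-in probes, RNA added in equal amount, also differed, at 13.06 ± 0.45 in control and 13.88 ± 0.18 in DEN/TAA (SD, n = 5 each). The 100 brightest spots held 34.5% ± 1.75 of the signal in control and 25.6% ± 1.49 in DEN/TAA (SD, n = 5 each). Control replicate 5 had the fewest spots above background, 16.5%.

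**Figure D1:**
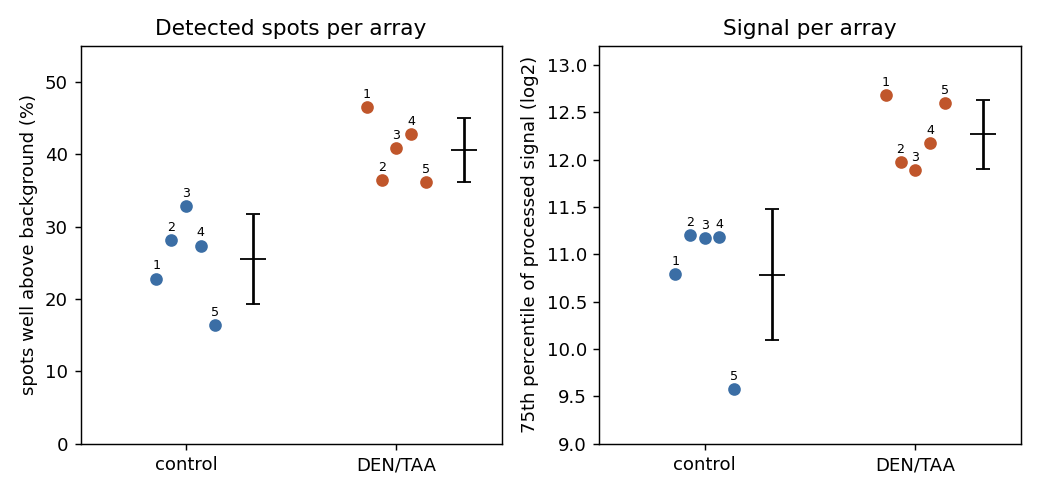
Share of spots well above background (left, percent) and 75th percentile of log2 processed signal over the probes detected on all arrays (right) for each array, numbered by replicate, with the mean and SD of each group of 5. Every control array lies below every DEN/TAA array, and control replicate 5 is the dimmest at 16.5%.

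The comparison asks which genes differ between treated and control liver. Akr1b8, an aldo-keto reductase, was at least 620-fold higher and Bex1 at least 99.1-fold higher, both above background on all 5 DEN/TAA arrays and on no control array (limma adjusted p = 1.29e-07 and 1.01e-07). Gstp1, the placental glutathione transferase used to mark altered foci in rat liver, rose by 5.92 on the log2 scale (SE 0.17), or 60.4-fold, and its 2 probes gave 5.92 and 7.83. Aldh3a1, an aldehyde dehydrogenase, rose by 6.83 (SE 0.42) and was above background on 3 of 5 control arrays, and Car2, carbonic anhydrase 2, rose by 5.81 (SE 0.22). By measured log2 difference, Serpinb1a (at least 29.9-fold), Pla2g7 (at least 28.6-fold) and Pcp4 (at least 23.7-fold) were also among the 10 largest rises. So were Ugt2b7 (at least 22.2-fold) and Defb1 (at least 15.3-fold), and none of these genes was above background on a control array. Their ranks thus rest on undetected control signals and need not hold by bound. Defb1 had a lower bound than Ggt1 (at least 16.0-fold). With its undetected control arrays raised to the floor, Cyp2c12 was 29.1-fold higher, above the bounds of Pla2g7, Pcp4, Ugt2b7 and Defb1.

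Among the 10 largest falls, Stac3 was at least 213-fold lower and Avpr1a, a vasopressin receptor, at least 67.9-fold lower, neither above background on any DEN/TAA array (limma adjusted p = 1.79e-11 and 3.14e-07). Obp3, a lipocalin of the urinary protein family, differed by -8.86 (SE 0.83), with 3 of 5 DEN/TAA arrays above background. The related urinary proteins Mup4, Mup4l1, Mup4l3, Mup4l4 and Mup5 differed by -7.54, -7.42, -7.37, -6.71 and -6.67, Mup4 being above background on 4 of 5 DEN/TAA arrays, and Cyp2c11, the main male-specific cytochrome P450, by -6.78 (SE 1.03). Members of the Mup family, and those of the Cyp2c family, are related in sequence, so probes of a family may share signal and the single genes are uncertain. How far the probes share sequence was not examined. Cyp2c11 and Cyp2c12 went in opposite directions (-6.78 and 5.26), so those 2 probes did not read the same signal. Lrtm2 differed by -6.09 (SE 0.48), with 3 of 5 DEN/TAA arrays above background.

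In all, 2669 of 6849 genes were higher in DEN/TAA and 1119 lower, 55.3% of those tested, and 1446 and 633 of these differed at least 2-fold. The groups did not overlap for 2697 genes, or 39.4%, where chance gives 0.794%. Of the higher genes, 566 were above background on no control array. The balance of directions depended on the scaling. Higher genes made up 70.5% of calls here, 31.0% with normexp (879 higher, 1959 lower), 58.8% with quantile normalisation (1936 and 1354), 60.8% in the authors' table (2036 and 1315), 50.2% with the percentile over all probes (1613 and 1597) and 91.9% with spike-in scaling (4449 and 394). With no filter on dim probes the share was 30.8% (2579 and 5804), and with a filter on all 10 arrays 54.9% (1152 and 948). Scaling subtracted on average 1.48 less (log2) from control arrays, so signal of unfiltered dim probes reads higher there. The median log2 difference of all genes tested was 0.32 here, -0.28 with normexp, 0.17 with quantile normalisation, 0.081 in the authors' table, 0.021 with the percentile over all probes and 0.99 with spike-in scaling, so changes are best read relative to it. Within each of the 3 slides, 2643 of the higher and 1110 of the lower genes differed in the same direction, and with slide as a block 2803 genes were higher and 1200 lower. The same arrays gave the calls, so the agreement within slides is not independent of them.

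**Figure D2:**
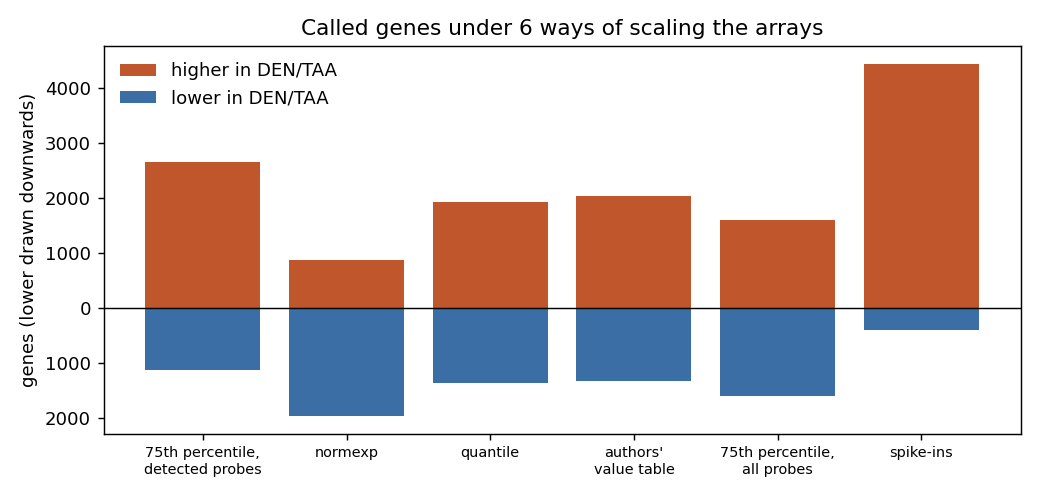
Number of genes called higher (upwards) and lower (downwards) in DEN/TAA under 6 ways of scaling the arrays. Higher genes range from 879 with normexp to 4449 with spike-ins, and lower genes from 394 with spike-ins to 1959 with normexp.

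Among the 35 gene lists tested, camera called 11 higher and 12 lower than other genes. Some lists share members, so they are not independent results. Abcc3, Akr7a3 and Ptgr1 are in both the NRF2 and the tumour marker lists, and Cps1 and Ass1 in both the urea cycle and the periportal lists. With an estimated correlation between genes only the NRF2 list was called. All 23 called lists had the same sign of mean in each of 6 scalings and within each of the 3 slides, and all 23 were called with slide as a block, which moved a list's mean by at most 0.33. Of the 12 uncalled lists, 3 kept their sign over the scalings. The slides hold the arrays that gave the calls, so their agreement is no independent support. Uncalled lists such as TGF-beta and PDGF, apoptosis and cholesterol also kept their sign within slides, while mast cell, Notch and Wnt, female-biased and ER stress lists did not. The number of members past the threshold depended on the scaling, and ranges in brackets after counts run over the 6 scalings. In 30 of the 35 lists the score reached the smallest exact permutation p, 0.00794. The score is not set against other genes, and 39.4% of single genes did not overlap between the groups, so this p singles out no list. The apoptosis list, not called by camera (adjusted p = 0.347), reached it too.

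**Figure D3:**
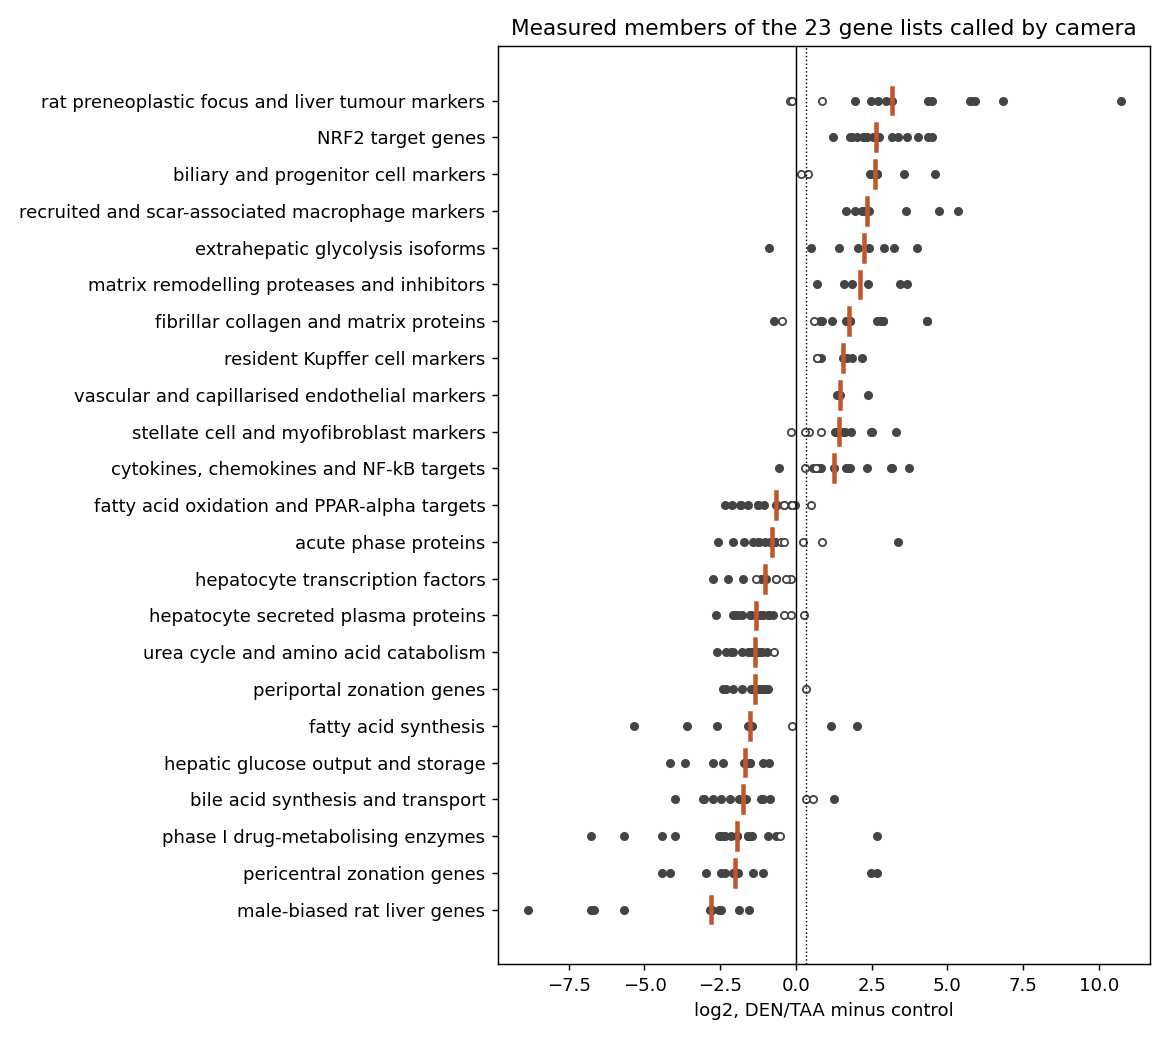
Log2 difference (DEN/TAA minus control) of each measured member of the 23 lists called by camera, with members past the adjusted p threshold filled, others open, the list median as an orange bar, and the dotted line at the median of all genes, 0.32. Medians run from -2.79 for male-biased genes to 3.18 for preneoplastic focus and tumour markers.

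Genes of oxidative stress defence rose together. All 17 measured NRF2 targets, among them genes of glutathione and thioredoxin, NADPH supply, detoxification and export, rose (14 to 17), with a median of 2.63 (2.33 with undetected genes at their bound) and a mean of 2.53 to 3.00 within slides (camera adjusted p = 6.98e-08; adjusted p = 0.0131 with an estimated correlation). Gclc, the catalytic subunit of glutathione synthesis, rose by 4.02 (SE 0.21), above background on 2 of 5 control arrays, and Txnrd1, thioredoxin reductase, by 3.38 (SE 0.14). Of the markers of rat preneoplastic foci and liver tumours, 12 of 15 rose (8 to 13) and 0 fell (0 to 1), with a median of 3.18 (2.66 with bounds) and a mean of 3.52 to 4.40 within slides (adjusted p = 2.19e-05; adjusted p = 0.0820 with an estimated correlation). Ggt1, gamma-glutamyltransferase, was at least 16.0-fold higher and Gpc3, a glypican of liver tumours, at least 1.49-fold higher, neither above background on a control array. Afp, the fetal serum protein, did not pass the threshold, at -0.21 (SE 0.27, adjusted p = 0.540).

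Matrix genes rose. Of 16 measured collagens and other matrix proteins 13 rose (8 to 14) and 1 fell (0 to 2), with a median of 1.74 (1.09 with bounds) and a mean of 1.56 to 1.91 within slides (adjusted p = 0.00277; adjusted p = 0.119 with an estimated correlation), and with the filter on all 10 arrays the list was not called (adjusted p = 0.130). Dcn, decorin, rose by 4.34 (SE 0.28), above background on 2 of 5 control arrays, or by 3.43 with the others raised to the floor. Col1a2 rose by 2.88 (SE 0.19). Col1a1 did not pass the threshold by its brighter probe, at 0.60 (SE 0.43, adjusted p = 0.254), while its other probe gave 3.98. With normexp, the mean over probes or spike-in scaling Col1a1 passed (2.14, 2.29 and 1.26). Col4a1 fell by 0.72, while its other probe gave 2.11, and the mean over probes gave 0.69. Its call ended with spike-in scaling (-0.056), without the 2 dimmest control arrays (-0.49), and without control replicate 2 or DEN/TAA replicate 5 (adjusted p up to 0.0562). All 6 measured remodelling proteases and inhibitors rose (3 to 6), with a median of 2.11 (1.72 with bounds) and a mean of 2.26 to 2.39 within slides (adjusted p = 0.00247; adjusted p = 0.0783 with an estimated correlation), among them Timp1, an inhibitor of metalloproteinases, by 3.68 (SE 0.20) and Mmp2 by 2.37 (SE 0.20), both above background on 4 of 5 control arrays. Of 12 stellate cell and myofibroblast markers 8 rose (4 to 11) and 0 fell (0 to 1), with a median of 1.43 and a mean of 1.01 to 1.60 within slides (adjusted p = 0.00782; adjusted p = 0.151 with an estimated correlation). Vim, the filament protein vimentin, rose by 3.32, above background on 4 of 5 control arrays, and Cygb, a stellate cell globin, by 2.46. In the TGF-beta and PDGF list 6 of 10 members rose (2 to 8) and 1 fell (1 to 2) without a call (median 1.76, 0.17 with bounds, adjusted p = 0.173). Ltbp1 and Pdgfa rose by 2.24 and 1.78, above background on 3 and 1 of 5 control arrays, and Inhba, a subunit of activin, differed by -3.62, above background on 4 of 5 DEN/TAA arrays.

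Markers of biliary, myeloid and vascular cells were higher. In the same rats the mean of the secreted plasma proteins of hepatocytes differed by -1.28, and 25.5% of spots were above background in control against 40.6% in DEN/TAA. Of 8 biliary and progenitor markers 6 rose (3 to 7) and 0 fell (0 to 1), with a median of 2.61 (1.35 with bounds) and a mean of 2.09 to 3.03 within slides (adjusted p = 0.00782; adjusted p = 0.119 with an estimated correlation). Krt19, a keratin of bile duct cells, was at least 9.91-fold higher and Epcam rose by 2.66, above background on 4 of 5 control arrays. All 9 recruited and scar-associated macrophage markers rose (8 to 9), with a median of 2.35 and a mean of 2.46 to 3.39 within slides (adjusted p = 5.01e-05; adjusted p = 0.119 with an estimated correlation). Lgals3, galectin-3, rose by 3.65 (SE 0.24), and Trem2, a lipid receptor of macrophages, was at least 5.32-fold higher. Of 8 Kupffer cell markers, those of the resident macrophages, 7 rose (5 to 8) and 0 fell (0 to 1), with a median of 1.56 and a mean of 0.46 to 1.97 within slides (adjusted p = 0.0244; adjusted p = 0.405 with an estimated correlation), including Folr2 by 2.18 and C1qb by 1.54. All 3 vascular endothelial markers rose (1 to 3), with a median of 1.46 (1.36 with bounds) and a mean of 1.35 to 2.15 within slides (adjusted p = 0.0382; adjusted p = 0.119 with an estimated correlation). Esam rose by 1.46, or 0.76 with the 4 control arrays where it was not above background raised to the floor, and Apln was at least 1.91-fold higher. That call ended with quantile normalisation, normexp, spike-in scaling, no filter and the replicate block, at adjusted p from 0.0506 to 0.223.

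Inflammatory genes rose, while lymphocyte and mast cell lists were not called. Of 15 cytokines, chemokines and NF-kB targets 12 rose (4 to 14) and 1 fell (0 to 1), with a median of 1.24 (0.81 with bounds) and a mean of 1.34 to 1.71 within slides (adjusted p = 0.0159; adjusted p = 0.261 with an estimated correlation). Cxcl10 rose by 3.75 on the log2 scale, and by 5.64-fold with the 4 control arrays where it was not above background raised to the floor. Ccl2 was at least 2.23-fold higher, and Il1a differed by -0.57, above background on 3 of 5 control arrays. Control is the group where Il1a read higher, and scaling makes signal near background read higher there, so its fall is uncertain. That list was not called with the filter on all 10 arrays (adjusted p = 0.0741). Of 7 T and NK cell markers 4 rose (0 to 7) without a call (median 0.93, 0.58 with bounds, adjusted p = 0.102), and Zap70 and Cd3g were at least 1.22-fold and 1.42-fold higher. Of 4 mast cell markers 2 rose (0 to 2) and 1 fell (0 to 2) (adjusted p = 0.796). Their median was 0.33 and their mean 0.42, against -0.26 for the median with bounds and a lower rank by camera. Cma1 was at least 1.23-fold higher, Tpsb2 passed the test as higher but its DEN/TAA mean lay below the floor of the control arrays, and Tpsab1 differed by -0.85. Of 4 sinusoidal endothelial markers 3 rose (2 to 4) without a call (median 1.09, adjusted p = 0.184; called with normexp and with no filter, adjusted p = 0.0307 and 0.0357), including Oit3 by 1.80 and Lyve1 by 1.20. Of 3 erythroid markers 2 rose (0 to 3) without a call (median 1.66, adjusted p = 0.263), Ahsp by 2.85 and Alas2 by 1.66, each above background on 1 of 5 control arrays. Lists with under 3 measured members were not tested: the neutrophil genes S100a8 (at least 9.46-fold) and S100a9 (by 3.89, above background on 2 of 5 control arrays) rose, the B cell factor Pou2af1 was at least 1.31-fold higher, and of 12 pancreatic acinar and adipocyte markers 1 was measured and did not pass the threshold.

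Genes of hepatocyte metabolism fell. Of 19 phase I drug-metabolising enzymes 17 fell (13 to 17) and 1 rose, with a median of -1.95 and a mean of -2.65 to -1.53 within slides (adjusted p = 1.72e-09; adjusted p = 0.0796 with an estimated correlation). Cyp1a2 differed by -4.43 (SE 0.36) and Cyp2d4 by -2.43 (SE 0.20), Cyp2e1, which activates thioacetamide, by -2.33 (SE 0.29), and Aldh1a1 rose by 2.67. All 10 genes of glucose output and storage fell (8 to 10), with a median of -1.69 and a mean of -2.41 to -1.58 within slides (adjusted p = 1.38e-07; adjusted p = 0.0783 with an estimated correlation), among them Pklr at -2.74 and Fbp1 at -1.50. Of 18 urea cycle and amino acid genes 17 fell (8 to 18), with a median of -1.36 and a mean of -1.81 to -0.78 within slides (adjusted p = 3.88e-10; adjusted p = 0.0985 with an estimated correlation), including Hpd at -2.13 and Ass1 at -2.07. Of 14 bile acid genes 11 fell (7 to 11) and 1 rose (1 to 2), with a median of -1.76 and a mean of -1.86 to -1.03 within slides (adjusted p = 1.03e-05; adjusted p = 0.119 with an estimated correlation). Slc27a5, which conjugates bile acids, differed by -4.01, the uptake carrier Slco1b2 by -2.48, and the export pump Abcc2 rose by 1.27.

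The fatty acid oxidation and synthesis lists were lower and the list of glycolysis isoforms higher. Of 17 fatty acid oxidation genes 10 fell (6 to 12) and 0 rose (0 to 2), with a median of -0.67 and a mean of -1.03 to -0.73 within slides (adjusted p = 5.54e-06; adjusted p = 0.119 with an estimated correlation), including Ehhadh at -2.33 and Acaa1a at -1.59. Of 8 fatty acid synthesis genes 5 fell (5 to 6) and 2 rose (1 to 2), with a median of -1.51 and a mean of -1.91 to -0.81 within slides (adjusted p = 0.00782; adjusted p = 0.302 with an estimated correlation), and the call ended with normexp (adjusted p = 0.0643) and with no filter (adjusted p = 0.259). Scd, the stearoyl-CoA desaturase, differed by -5.34 and Dgat2 by -1.44, while Me1 and Elovl6 rose by 2.01 and 1.14, Elovl6 being above background on 4 of 5 control arrays. The call of Elovl6 ended in 8 of the 10 fits that left out 1 rat (adjusted p from 0.000805 to 0.0984). The cholesterol list was not called (median -0.60, adjusted p = 0.0672), with 4 of 12 lower (0 to 7) and 1 higher (1 to 3). With spike-in scaling it ranked lower than other genes (adjusted p = 0.0334) although its mean was 0.41, with 3 members higher and 0 lower, where the median of all genes was 0.99. It was also called lower without control replicate 2 or DEN/TAA replicate 1 (adjusted p from 0.0233 to 0.123 over the 10 fits that left out 1 rat). Insig1 and Fdps differed by -1.20 and -0.97, calls that ended with spike-in scaling (-0.53 and -0.30). Of 8 measured members of the glycolysis list 7 rose (6 to 7) and 1 fell (0 to 1), with a median of 2.23 and a mean of 1.72 to 2.05 within slides (adjusted p = 0.0159, and 0.119 with an estimated correlation). Ldhb was at least 5.75-fold higher, Aldoa rose by 2.91, above background on 4 of 5 control arrays, and Ldha differed by -0.88, a call that ended with spike-in scaling (-0.21).

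The secreted plasma protein and acute phase lists were lower, and for both the number of members that fell depended on the scaling. Of 19 plasma proteins 16 fell (9 to 16) and 0 rose (0 to 1), with a median of -1.31 and a mean of -1.32 to -1.18 within slides (adjusted p = 9.49e-11; adjusted p = 0.0509 with an estimated correlation), including Apoa2 at -2.63 (SE 0.18) and Apoc3 at -2.06 (SE 0.14). Alb differed by -0.92 (SE 0.26, adjusted p = 0.00931), a call that ended in the authors' table (-0.15) and with spike-in scaling (-0.26) and turned to 0.15 with quantile normalisation. Of 17 acute phase proteins 12 fell (5 to 13) and 1 rose (1 to 2), with a median of -0.78 and a mean of -0.85 to -0.36 within slides (adjusted p = 1.03e-05; adjusted p = 0.151 with an estimated correlation), and quantile normalisation ended the call (adjusted p = 0.108). Only 5 of the acute phase proteins were lower with quantile normalisation (1 higher, mean -0.20), in the authors' table (2 higher, mean -0.27) and with spike-in scaling (2 higher, mean -0.010). Crp and Itih3 differed by -2.56 and -2.06, and A2m, alpha-2-macroglobulin, rose by 3.38 (SE 0.40). Of 12 hepatocyte transcription factors 6 fell (3 to 11) and 0 rose, with a median of -1.01 and a mean of -1.24 to -0.77 within slides (adjusted p = 5.01e-05; adjusted p = 0.0820 with an estimated correlation), including Onecut1 at -2.74 and Foxa1 at -2.26, the last above background on 4 of 5 DEN/TAA arrays.

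**Figure D4:**
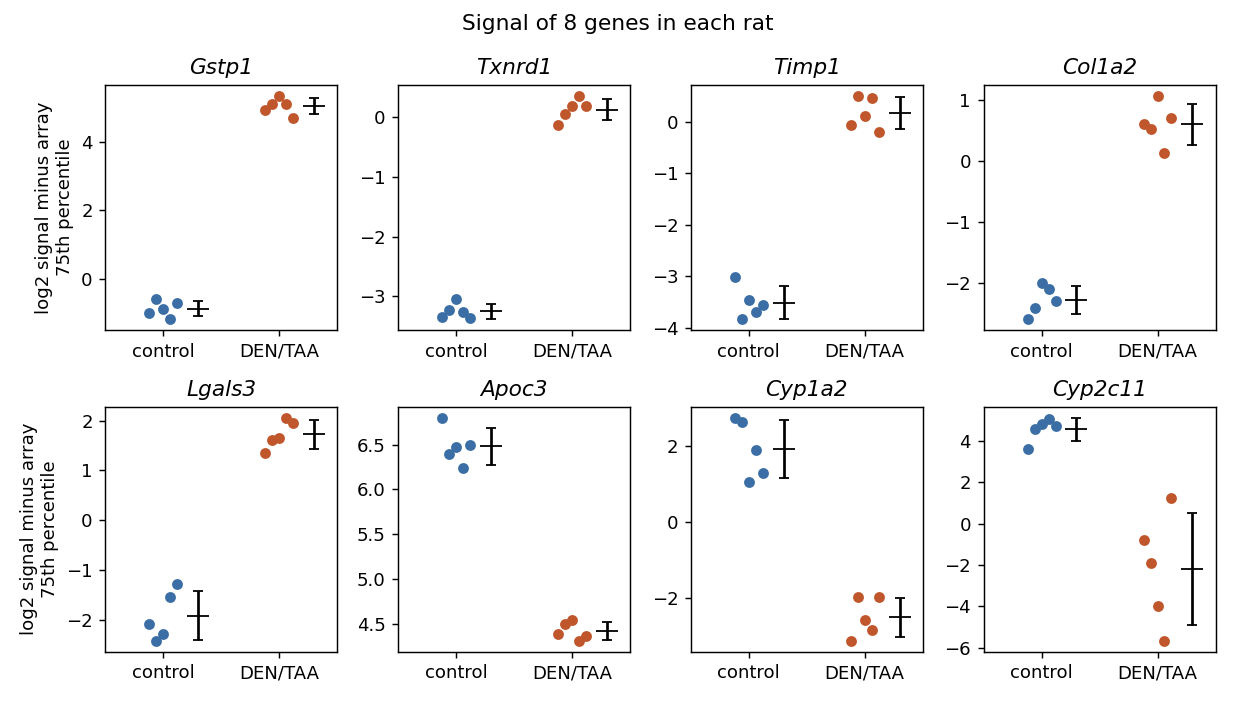
Log2 signal minus the array's 75th percentile of 8 genes in each rat, with the mean and SD of each group of 5. Gstp1, Txnrd1, Timp1, Col1a2 and Lgals3 are higher in all 5 DEN/TAA rats than in any control rat and Apoc3, Cyp1a2 and Cyp2c11 lower, with an SD of 2.70 for Cyp2c11 in DEN/TAA.

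Sex-biased genes moved unevenly. All 11 genes with higher expression in male rat liver fell, with a median of -2.79 and a mean of -5.64 to -2.92 within slides (adjusted p = 3.61e-08; adjusted p = 0.136 with an estimated correlation), including Obp3, above, and Rgn, regucalcin, at -1.56 (SE 0.22). The 5 DEN/TAA rats differed widely in this list's score, from -3.86 to -0.47, against 1.09 to 2.61 in control. Of 5 genes with higher expression in females 2 rose and 2 fell (2 to 3) (adjusted p = 0.352). Their median of -1.57 and lower rank by camera differed in sign from their mean of 0.46. Cyp2c12 and Akr1b7 rose by 5.26 and 4.72, above background on 2 and 1 of 5 control arrays, or by 4.86 and 2.93 with the others raised to the floor. Cyp2c7 and Cyp2a1 differed by -3.99 and -1.57.

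Genes of both liver zones fell. Of 12 pericentral genes 10 fell (8 to 10) and 2 rose, with a median of -2.01 and a mean of -1.95 to -1.04 within slides (adjusted p = 1.03e-05; adjusted p = 0.0968 with an estimated correlation). Oat, ornithine aminotransferase, differed by -4.17, and Rhbg, an ammonium transporter, rose by 2.47, above background on 3 of 5 control arrays. Of 12 periportal genes 11 fell (5 to 11) and 0 rose (0 to 1), with a median of -1.37 and a mean of -1.48 to -0.97 within slides (adjusted p = 5.54e-06; adjusted p = 0.0567 with an estimated correlation), including Cyp2f4 at -1.47. The pericentral minus periportal score was -2.16 ± 0.12 in DEN/TAA and -1.90 ± 0.29 in control (SD, n = 5 each), a difference of -0.26 that did not pass the exact permutation test (p = 0.103) and was -0.47, -0.30 and -0.071 within slides. Every treated rat lay below the controls of its own slide, but permuted within slides the difference did not pass either (exact permutation p = 0.0741). The difference passed with normexp (-0.36, p = 0.0159), quantile normalisation (-0.39, p = 0.0397), the authors' table (-0.21, p = 0.0397), the filter on all 10 arrays (-0.64, p = 0.00794) and without control replicate 4, all by exact permutation.

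Cell cycle and stress lists were not called. Of 14 cell cycle genes 9 rose (2 to 11) and 0 fell (0 to 4), with a median of 1.03 (0.087 with bounds; adjusted p = 0.0839), including Tyms, above background on 1 of 5 control arrays, and Pcna by 2.00 and 1.48. The list was called with quantile normalisation, the percentile over all probes, no filter and without the 2 dimmest control arrays (adjusted p from 0.00216 to 0.0393). With normexp 2 cell cycle genes were higher and 4 lower, with a mean of -0.22. Normexp also brought below 0 the means of the TGF-beta and PDGF (-0.17, 2 higher and 2 lower), apoptosis (-0.19, 1 and 2), T and NK cell (-0.36, 0 and 0), mast cell (-0.75, 0 and 2), Notch and Wnt (-0.38, 0 and 1), female-biased (-0.39, 2 and 3) and ER stress (-0.32, 2 and 4) lists. The median of all genes was -0.28 there. Relative to other genes the cell cycle (0.041), TGF-beta and PDGF (0.087) and apoptosis (0.066) means stayed higher, and those of the other lists just named were lower. Of 14 p53 targets 8 rose (5 to 9) and 0 fell (0 to 2), with a median of 1.30 (0.93 with bounds; adjusted p = 0.0525). Zmat3 and Fas, both above background on 4 of 5 control arrays, rose by 2.23 and 2.17 and Cdkn1a, the cell cycle inhibitor p21, by 1.88 (SE 0.43). That list was called in 6 of the 10 fits that left out 1 rat (adjusted p from 0.0202 to 0.117), in the authors' table, with no filter and with the percentile over all probes (adjusted p from 0.000370 to 0.0482). Of 14 apoptosis regulators 5 rose (1 to 11) and 1 fell (1 to 2) (median 0.47, 0.37 with bounds, adjusted p = 0.347). Bak1 and Birc3 rose by 2.78 and 1.56, above background on 3 and 2 of 5 control arrays, and Bmf differed by -3.62, above background on 3 of 5 DEN/TAA arrays. With no filter that list and the TGF-beta and PDGF list were called (adjusted p = 0.0103 and 0.0357). Of 10 ER stress genes 2 rose (2 to 4) and 2 fell (1 to 5) (adjusted p = 0.194), with a median of -0.35 and a lower rank by camera but a mean of 0.11. Asns was at least 4.05-fold higher, Atf3 rose by 2.89, above background on 2 of 5 control arrays, and Chac1, above background on 4 of 5 DEN/TAA arrays, and Herpud1 differed by -2.71 and -0.93. Of 3 Notch and Wnt genes 2 rose (0 to 2) and 1 fell (0 to 1) (adjusted p = 0.796), with a median of 0.73 and a mean of 0.27 but a lower rank by camera. Jag1 and Notch3 rose by 1.07 and 0.73, Jag1 being above background on 2 of 5 control arrays, and Hes1 differed by -0.97, above background on 3 of them. Control is the group where Hes1 read higher, and scaling makes signal near background read higher there, so its fall is uncertain. The call of Notch3 ended in 7 of the 10 fits that left out 1 rat (adjusted p from 0.00393 to 0.112). Adjusted over the list alone, the counts of changed members differed from these only for the stellate (9 higher), cell cycle (10 higher), cytokine (13 higher), cholesterol (3 lower) and female-biased (3 lower) lists.

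Among genes named above, normexp ended the calls of Ahsp (0.98), Alas2 (0.055), Apln (0.11), Ccl2 (0.49), Elovl6 (0.35), Esam (0.10), Gpc3 (0.11), Lyve1 (0.62), Notch3 (0.63), Pdgfa (0.012) and Tyms (0.38). It turned Birc3 (-0.23), Cd3g (-0.28), Cma1 (-0.15), Jag1 (-0.38), Pou2af1 (-0.096), Tpsb2 (-0.79) and Zap70 (-0.28), none of which passed there. Spike-in scaling, which raised every gene by the same amount (to a median of 0.99), ended the calls of Herpud1 (-0.27), Hes1 (-0.31) and Tpsab1 (-0.19) and turned Afp (0.46) and Il1a (0.090), which did not pass there. The authors' table ended the calls of Alas2 (0.44, adjusted p = 0.0802), Birc3 (0.23, adjusted p = 0.0590), Elovl6 (0.44), Il1a (-0.18), Jag1 (0.17), Notch3 (0.60, adjusted p = 0.0507) and Tpsb2 (0.12), besides Alb. Quantile normalisation ended those of Elovl6 (0.80), Jag1 (1.06) and Notch3 (0.70), and so did the percentile over all probes (0.84, 0.77 and 0.42). Without the 2 dimmest control arrays the calls of Fdps (-0.81), Il1a (-0.42) and Notch3 (0.70) ended, with array weights that of Fdps (-0.78), with no filter that of Notch3 (adjusted p = 0.0582) and with slide as a block that of Elovl6 (adjusted p = 0.0543). For 33 named genes above background on only some arrays of the lower group, raising that group's other arrays to the floor kept every direction but moved the difference by up to 1.79. For genes above background on 1 or 2 control arrays it gave, for example, 2.93 (Akr1b7), 1.89 (Ahsp), 1.29 (Tyms), 1.09 (Pdgfa), 1.00 (Alas2), 0.88 (Birc3) and 0.26 (Jag1).

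The median distance of a rat from the rest of its group was 0.22 ± 0.073 in DEN/TAA and 0.32 ± 0.075 in control (log2, SD, n = 5 each), a difference that did not pass the exact permutation test (p = 0.0714). It was -0.14, -0.048 and -0.0099 within slides, and passed when rats were permuted within slides (exact permutation p = 0.0370). The first principal component held 71.5% of the variance and separated the groups. The second held 9.57% and placed the 3 arrays of slide 3 between -31.9 and -20.7 and the other 7 between 2.07 and 30.6.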

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

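The tests of scaling, hepatocyte share and sex-biased genes in this part were chosen after the results were seen; the tests of array brightness and of other groupings were set down before their outcome was known.

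In 16 of 302 groups of 5 values checked, or 5.30%, 1 rat stood far from the other 4 (gap over range above 0.71), about the 1 in 20 that chance gives. DEN/TAA replicate 5, the 1 treated rat on slide 3, stood apart in 6 of them: lower for Apln (-4.84), Col4a1 (-2.21), Notch3 (-0.56) and Pdgfa (-4.46), higher for the urea cycle and amino acid score (-0.064), and farther from its group (0.35). DEN/TAA replicate 4 stood apart for Cma1 (-5.63), Rhbg (-3.21), S100a8 (-0.66) and Slco1b2 (-2.87). Control replicate 1 had the highest Cyp2c12 (-3.07) and acute phase score (4.32) and the lowest stellate cell (-4.50) and glucose output (0.90) scores. Control replicate 5 had the highest C1qb (1.43) and Mup5 (6.96). Outside the named genes, 1871 probes without a gene symbol here were higher in DEN/TAA and 637 lower, of 5880 past the filter.

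Other groupings of the 10 rats bear on the counts. Of 100 splits into 5 and 5, the real one included, 1 gave as many called genes (3788, against at most 30 in another split) and 1 as many of at least 2-fold (2079, against at most 26). For both this is the smallest share that 100 splits can give, which does not exclude chance. Groups that mix treated and control rats have a wider spread, which itself lowers their counts of called genes. For called lists, 3 of 100 splits gave as many (23 in the real split and at most 23 in another), a share under 0.05 without a margin. This bears on the count at camera's preset correlation and on no single list, since with an estimated correlation only 1 list was called. Every other split still holds part of the treatment difference. The 22 splits that exchanged 1 rat per group, which set 4 treated rats against 1, gave 15 to 23 called lists (median 20.5), and the 77 that exchanged 2 gave 0 to 19 (median 7).

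The first pattern is the excess of higher over lower genes beside dimmer control arrays, and for that balance brightness stays open, since the values were already scaled by it. Brightness left after scaling was examined for the differences of at least 2-fold, by its slope within groups multiplied by the brightness difference. For genes at least 2-fold higher this gave -0.043 (95% interval -0.29 to 0.20) against a median difference of 1.91. For those lower it gave 0.28 (-0.26 to 0.81) against -1.88. This slope cannot decide whether brightness was a cause. The values already had that brightness subtracted, and the genes were picked by a test that favours a small spread within groups. Brightness also did not overlap between groups (at most 11.20 in control, at least 11.89 in DEN/TAA), so the slope had to reach across a gap without arrays. The choice of scaling could set the balance itself, since higher genes ranged from 31.0% to 91.9% of calls over 5 other scalings. So could the filter on dim probes: the share was 70.5% here, 54.9% with the filter on all 10 arrays and 30.8% with none. The filter used here kept 682 genes above background on no control array, against 2 above background on no DEN/TAA array. Whether treated livers hold more RNA per unit of input is open, and the treatment stays among the explanations.

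The second pattern is the fall of hepatocyte lists beside the rise of other cells' markers. A lower share of hepatocytes alone would raise other cell types alike. The recruited macrophage score rose by 1.97 more than the sinusoidal endothelial score (exact permutation p = 0.00794). That pair was picked after the results were seen and lay far apart, with means of 2.95 and 0.98. Biliary (2.39), stellate (1.44), Kupffer (1.38) and T and NK cell (1.17) lists lay between, and mast cell markers lower (0.42). The p-value of a pair picked in this way cannot decide whether share was the whole cause of those rises. For the falls, the phase I score differed by -0.95 beyond the secreted protein score (95% interval -1.63 to -0.26, exact permutation p = 0.0159), and every treated rat lay below the controls of its slide (-0.83, -1.46 and -0.22 within slides, p = 0.0185 permuted within slides), so the falls were unequal. Cyp2a2, Cyp2c11, Cyp2c13 and Cyp3a2 belong to both the phase I and the male-biased lists. Part of the gap is thus the fall of male-biased genes, and no score without them was computed. The interval and slide 3 reach gaps under the 0.5 log2 set as the limit for falls that count as alike, so a lower share and a change within hepatocytes cannot be told apart for those lists.

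The third pattern is the fall of male-biased genes. Their score differed by -2.80 beyond that of secreted proteins (95% interval -4.29 to -1.31, exact permutation p = 0.00794), so these lists fell unequally. That pair was picked after the results were seen, and set the largest fall (mean -4.08) against a smaller one (-1.28). Phase I (-2.23) and glucose (-2.14) lists lay between. The p-value thus cannot decide whether a general fall of hepatocyte genes was the whole cause. Signal shared within the Mup family cannot by itself give the fall of the 9 members outside it (median -2.78). That all 9 fell was already known from the fall of all 11 members. A switch to the female pattern may be biological but is not settled: female-biased genes went both ways, 2 higher and 2 lower (camera adjusted p = 0.352).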

How the results depend on the processing

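Scaling to all probes or spike-ins and leaving out the 2 dimmest control arrays were chosen after the data were seen. Normexp gave 879 genes higher, 1959 lower and 375 at least 2-fold higher, and the authors' table gave 351 at least 2-fold higher and 389 lower. Spike-in scaling gave 4449 higher, 394 lower, 3368 at least 2-fold higher and 296 lower, and the percentile over all probes 1613 higher. With no filter 5804 of 13825 genes were lower, 5322 at least 2-fold. That setting adds probes near background, where scaling makes control read higher, so these counts do not measure falls of expression. With the filter on all 10 arrays, which tests 3568 genes, 1152 were higher, 350 at least 2-fold, and 5 lists were called higher. Camera with an estimated correlation called 1 list higher and 0 lower (4 and 9 at an unadjusted p under 0.05), and fry 18 higher. Other causes were not tested.

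Directions turned for Birc3 (-0.23), Cd3g (-0.28), Cma1 (-0.15), Jag1 (-0.38), Pou2af1 (-0.096), Tpsb2 (-0.79) and Zap70 (-0.28) with normexp, where the shifts of the T and NK (-0.11), mast cell (-0.49) and female-biased (-0.13) lists also turned. They turned for Alb with quantile normalisation (0.15), Col4a1 with the mean over probes (0.69), and Afp (0.46) and Il1a (0.090) with spike-in scaling, which raised every gene alike. In the authors' table the mast cell (-0.11), Notch and Wnt (0.078) and female-biased (-0.15) shifts turned, and with no filter the cholesterol (0.017) and ER stress (0.48) shifts. Causes were not tested.

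The pericentral minus periportal difference passed its exact permutation test with normexp (-0.36, p = 0.0159), quantile normalisation (-0.39, p = 0.0397), the authors' table (-0.21, p = 0.0397) and the filter on all 10 arrays (-0.64, p = 0.00794). The spread between rats did so with normexp (-0.21, p = 0.0238), the authors' table (-0.060, p = 0.0317), no filter (-0.32, p = 0.00794) and permutation within slides (-0.10, p = 0.0370).

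Leaving out 1 rat gave 2324 to 2674 higher genes, 989 to 1147 lower, 1380 to 1516 and 590 to 670 at least 2-fold, 11 to 12 lists higher and 12 to 13 lower. The zone difference ran from -0.34 to -0.17 and passed without control replicate 4, and the spread from -0.14 to -0.071, passing without control replicate 2, control replicate 3 or DEN/TAA replicate 5. The mast cell shift ran from -0.12 to 0.26 and the female-biased one from -0.16 to 0.55. Calls ended for Elovl6 in 8 fits, Notch3 in 7 and Col4a1 in 2 (without control replicate 2 or DEN/TAA replicate 5). Without the 2 dimmest control arrays 2583 genes were higher and 1116 lower.

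Replicate numbers were not taken as pairs, because same-number correlations of deviations ran from -0.22 to 0.20 and not all 5 were over 0.1. For 3 of 5 numbers the best partner had the same number, a hint from the data that the shared slides could also give (mean correlation 0.16 within slides). With the replicate block the cholesterol list was called (adjusted p = 0.0389) and the vascular list was not (adjusted p = 0.0524), and 2663 genes were higher and 1121 lower, and 10 lists were called higher and 13 lower. Dim control arrays limit what can be measured there: 682 of the genes tested were above background on none of them.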

Other observations

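The gene families below, formed by the letters that open a symbol, were chosen and tested after the data had been seen. Cytosolic ribosomal protein genes were higher: 23 of 30 Rps genes passed the threshold as higher and 0 as lower (median 0.64, camera adjusted p = 0.00824; adjusted p = 0.721 with an estimated correlation), as did 32 of 45 Rpl genes (median 0.55, adjusted p = 0.0180; adjusted p = 0.761 with an estimated correlation). Their medians were above 0 under all 6 scalings, from 0.34 to 1.31 for Rps and from 0.25 to 1.21 for Rpl. Of 14 nucleoporin genes (Nup) 11 were higher (median 0.74, adjusted p = 0.0319; adjusted p = 0.620 with an estimated correlation), and the median was above 0 under all 6 scalings. Of 49 cytochrome P450 genes (Cyp) 38 were lower and 7 higher (median -1.54, adjusted p = 1.16e-11; adjusted p = 0.620 with an estimated correlation), and of 16 hydroxysteroid dehydrogenase genes (Hsd) 13 were lower and 1 higher (median -1.05, adjusted p = 7.60e-06; adjusted p = 0.455 with an estimated correlation), both with medians below 0 under all 6 scalings.

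Of 17 olfactory receptor genes (Or) that passed the filter on dim probes 8 were lower and 0 higher (median -0.59, camera adjusted p = 2.03e-04; adjusted p = 0.620 with an estimated correlation). Their median was below 0 under 5 scalings and 0.07 with spike-in scaling, where the median of all genes was 0.99. Scaling subtracted on average 1.48 less (log2) from control arrays than from DEN/TAA arrays, so signal near background reads higher in control. How near background these genes lay was not examined, so a fall of their expression cannot be told from that effect.

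Of 73 families with at least 10 members, camera called 4 higher and 6 lower. Besides those described, S (8 of 10 higher, median 3.02) was called higher, and Pex (4 of 14 lower, median -0.32, and 0.34 with spike-in scaling, where the median of all genes was 0.99), Slc (45 of 135 lower and 37 higher, median -0.048) and Ndufb (2 of 10 lower, median -0.28) lower. With an estimated correlation camera called 0 (smallest adjusted p = 0.455; 3 at an unadjusted p under 0.05). A second grouping, with at least 8 members and 3 families set apart by hand after the first had been seen, gave 4 higher and 9 lower of 109, and 0 with an estimated correlation (smallest adjusted p = 0.187; 7 at an unadjusted p under 0.05).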
